A study of Mus musculus with 6 samples.

How the data were processed

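Splenic CD4+ CD25+ T cells, the surface phenotype of regulatory T cells (Treg cells), were profiled on 6 expression arrays: 3 from mice in which Vav-driven Cre recombinase removes a floxed Keap1 gene from blood-forming cells (Keap1_KO, replicates B, C and D) and 3 from wild-type mice (WT, replicates A, D and F). Per the labels' protocols, cells were isolated from the spleens of untreated mice by magnetic separation, total RNA was purified with a small-sample column kit, and 40 ng was amplified into biotin-labelled cDNA with a whole-transcriptome kit. The labels give all 6 samples as male and C57BL/6. They give the age as 10 to 12 months in the sample characteristics and 6 to 10 weeks in the growth protocol, and this conflict stays open. The series title writes the cells as CD4-negative, whereas every sample label writes CD4+. The series design text calls the triplicates independent and does not say that each array is a separate mouse, so the p-values measure the spread between these arrays, part of which may be technical. Groups and replicate letters were taken from the sample titles.

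The deposited values are log2 expression values, 1 per transcript cluster and array. Per the submitters' processing notes, Affymetrix Expression Console, RMA and Transcriptome Analysis Console were used, with no versions or roles given. RMA corrects background, quantile-normalizes arrays and summarises probes on the log2 scale. The genome build is not given in the sources used here, so no coordinates are printed. The series design text names a Mouse Gene array, whereas the 65528 row identifiers match an annotation table made for a different Affymetrix mouse array, and names were taken through that match. The lowest value was 1.88 and the highest 19.93. A 16-bit scanner cannot exceed 16 on the log2 scale, and 1268 clusters exceeded it on at least 1 array, so a further rescaling that no source states stands between the scanner and these values. Fold changes are on the deposited scale. Array medians over all clusters lay between 5.16 and 5.43. For arrays the number of arrays limits the precision, and no read depth applies. Every value column was mapped to a sample.

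Of the 65528 clusters, 30354 carried 1 gene symbol, 2118 carried several and 33056 were unnamed here. Symbols were updated through the Entrez identifier for 22586 clusters, which replaced 824 names. Clusters with several symbols were not attributed to a gene. Foxp3 and Gclm sit on such shared clusters. A cluster was tested when its value was at or above the median of its array on at least 3 of the 6 arrays, and where a symbol had several clusters passing this filter (148 genes) the cluster with the highest mean stood for the gene. This left 16825 genes, of which 10996 were protein-coding and 1403 were genes of small RNAs (microRNA, snoRNA and snRNA).

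Keap1_KO was compared with WT by limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 16825 genes and a threshold of adjusted p under 0.05. Single values were also compared by an exact two-sided permutation test, whose smallest possible p with 3 arrays against 3 is 0.1. Gene lists were compared by limma camera with a preset inter-gene correlation of 0.01, adjusted over the lists tested, with camera using an estimated correlation and fry beside it. A list needed 3 tested genes. The 35 lists were NRF2 core targets, glutathione metabolism, thioredoxin and peroxiredoxin system, NADPH and pentose phosphate pathway, heme and iron handling, Treg signature, naive and central memory T cell, Th1 and cytotoxic effector, Th2 effector, Th17 and Tfh, coinhibitory and exhaustion, cell cycle, glycolysis, oxidative phosphorylation, ATF4 and amino acid response, cholesterol synthesis, fatty acid synthesis, type I interferon response, immediate early genes, heat shock, proteasome, p53 targets, circadian clock, sex genes, CD4 T cell identity, and markers of B cells, plasma cells, CD8 T cells, NK cells, macrophages and monocytes, neutrophils and granulocytes, dendritic cells, erythroid cells, platelets and megakaryocytes, and stroma and endothelium. Lists share members: several NRF2 targets also stand in the glutathione and thioredoxin lists.

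The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Keap1, Nfe2l2, Foxp3, Il2ra, Ctla4, Ikzf2, Nqo1, Hmox1, Gclc, Gclm, Txnrd1, Srxn1, Slc7a11 and Gsr, then the 12 genes with the largest rise and the 12 with the largest fall among genes past the adjusted threshold whose groups do not overlap. Where fewer than 6 pass in a direction, that direction is filled to 6 by the largest fold among genes with unadjusted p under 0.01 and no overlap, described as not past the adjusted threshold. Up to 4 members of each list are named, those past the threshold or else those with the largest fold, given as values. The filled part leaves out predicted genes, small RNA genes and single immunoglobulin and T cell receptor segments, and sex genes serve only as a label check. Other genes are named only where the text says that they were chosen after their values were seen.

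On simulated data with the measured means and residual spreads of the 16825 genes and 200 genes changed by known amounts, the same steps recovered 20.9% of 67 genes changed by log2 1, 71.6% of 67 changed by log2 2 and 90.9% of 66 changed by log2 4, with 8 false calls. A simulated shift of log2 1 in the glutathione list was called, and the call of 1 other list, NRF2 core targets, came with the members that it shares. The simulated noise was drawn independently for each gene and array. It held no array-wide component and no correlation between genes. These rates therefore do not show how often genes or lists are falsely called in the measured data. Alternatives covered the filter, the handling of several clusters per gene, clusters without a symbol, the normalization, the spread estimate, array weights, thresholds, leaving out each array in turn, and, added after the data had been seen, covariates for array-wide signal and for neutrophil markers, protein-coding genes alone, and leaving out a pair of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.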

Results

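CD4+ CD25+ T cells from the spleens of Keap1_KO and WT mice were compared on 3 expression arrays per genotype, to see how the transcriptome of cells with the Treg surface phenotype differs when Keap1 is deleted in blood-forming cells. Keap1 encodes the adaptor that marks the transcription factor NRF2 (gene Nfe2l2) for degradation. Values are deposited log2 RMA values, given as mean ± SD over 3 arrays per group unless stated otherwise, and differences are Keap1_KO minus WT. Correlations between arrays across the 16825 genes tested ranged from 0.958 to 0.983 within a genotype and from 0.927 to 0.988 between genotypes. The closest pair joined both genotypes, WT A and Keap1_KO B. Y-linked Uty (9.75 ± 0.11 in WT and 9.40 ± 0.29 in Keap1_KO) was expressed and Xist was low (5.49 ± 0.19 and 5.30 ± 0.13), which fits the male labels.

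The targeted gene was measured first. Keap1 read 5.30, 5.41 and 5.77 on WT A, D and F and 4.87, 4.89 and 4.70 on Keap1_KO B, C and D, so each Keap1_KO array lay below each WT array. The difference was -0.67 (SE 0.15), the exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow, and the limma adjusted p was 0.563. Keap1 lay below the intensity filter on most arrays, so its values come from the fit without that filter, and probes outside the floxed part of the gene would not report its loss. Nfe2l2 read 8.93 ± 0.63 in WT and 9.94 ± 0.81 in Keap1_KO, and the arrays overlapped (exact permutation p = 0.2).

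**Figure D1:**
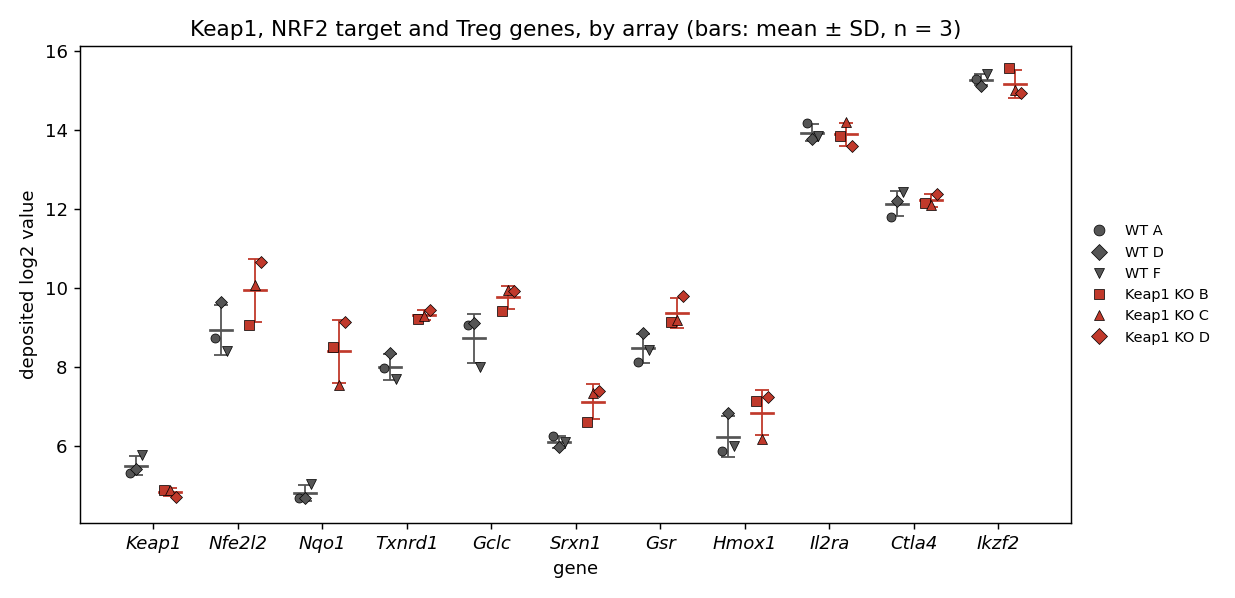
Deposited log2 values (vertical axis) of 11 genes on the 6 arrays, with 1 symbol per array, horizontal lines for group means and bars for the SD of 3 arrays. Nqo1 lies between 4.68 and 5.03 on the WT arrays and between 7.55 and 9.14 on the Keap1_KO arrays, whereas the Il2ra, Ctla4 and Ikzf2 values of the genotypes overlap.

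Genes regulated by NRF2 were higher in the Keap1_KO cells as a set. Of 26 NRF2 core targets tested, 25 had a higher mean in Keap1_KO, the median difference was 0.94 (1.92-fold), and limma camera gave an adjusted p of 2.24e-09. The call did not hold with an estimated correlation (p = 0.0932, adjusted p = 0.679). For the lists in the following paragraphs, the camera p with an estimated correlation is given before adjustment unless stated otherwise. After adjustment it was 0.679 for every list that passed with the preset correlation. Nqo1, a quinone reductase and a standard readout of NRF2 activity, averaged 4.80 ± 0.20 in WT and 8.40 ± 0.80 in Keap1_KO. Its deposited values differed 12.1-fold, but each WT value lay below the median of its array, so this fold is not exact. Txnrd1, which encodes thioredoxin reductase, read 7.99 ± 0.33 against 9.31 ± 0.12 (2.50-fold), and Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, read 8.72 ± 0.63 against 9.76 ± 0.29 (2.05-fold). The sulfiredoxin gene Srxn1 (2.02-fold) and the glutathione reductase gene Gsr (1.87-fold) also had all Keap1_KO values above all WT values.

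Adjusted over the list alone, 14 of the 26 NRF2 targets passed, all of them higher in Keap1_KO, and over all genes tested none did. Nqo1 had limma adjusted p = 0.00192 over the list alone and 0.310 over all genes. The values over the list alone were 0.00833 for Txnrd1, 0.0263 for Srxn1 and 0.0415 for Gclc and Gsr. Glutathione S-transferase genes, a family with near-identical members that probes may not separate, gave the next largest differences, with 2.87 for Gstm1 and 2.64 for Gstp1, followed by 1.69 for Taldo1, an enzyme of the pentose phosphate pathway. For Gstp1 the arrays overlapped, with Keap1_KO B (11.14) below WT D (11.37). Hmox1, which breaks down heme, read 6.23 ± 0.51 and 6.84 ± 0.58 and the arrays overlapped. Slc7a11, the cystine transporter gene, was dim, at 4.92 ± 0.12 and 5.52 ± 0.67, and the cluster that Gclm shares with a predicted gene read 7.99 ± 0.29 and 8.51 ± 0.17. Limma fry, which tests the direction of the set without comparing it with other genes, gave an adjusted p of 0.196 (0.0185 before adjustment). The mean deviation of the list was -0.60, -0.25 and -0.86 on WT A, D and F and 0.01, 0.70 and 0.998 on Keap1_KO B, C and D.

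Related redox lists were higher too. All 14 tested genes of the thioredoxin and peroxiredoxin system had higher means in Keap1_KO (median 0.81, camera adjusted p = 2.08e-05, p = 0.164 with an estimated correlation), and 3 of them, Txn1, Txnrd1 and Srxn1, passed adjusted over the list alone. Catalase, which removes hydrogen peroxide, read 9.51 ± 0.81 and 11.12 ± 0.62, and the cytosolic superoxide dismutase gene Sod1 read 15.40 ± 0.58 and 16.88 ± 0.86. Of 23 glutathione genes, 21 had higher means (median 0.79, camera adjusted p = 7.90e-06, p = 0.0839 with an estimated correlation). Gstm1 and the export pump gene Abcc1, the latter named after its values were seen, passed adjusted over that list alone, and the glutaredoxin gene Glrx differed by 1.74 and Gpx1 by 1.33. The 13 genes of NADPH production and the pentose phosphate pathway had a median of 0.32 (camera adjusted p = 0.043, p = 0.388 with an estimated correlation), with 1.02 for Pgls and 0.77 for Pgd. That median was 0.53 without Keap1_KO B, and the call was lost without WT F (median 0.21, adjusted p = 0.176), without Keap1_KO C (0.25, 0.0599), without Keap1_KO D (0.20, 0.128) and after repeated quantile normalization (0.20, 0.117), and over all 17 alternatives its camera adjusted p ranged from 0.00115 to 0.755. The arrays of the genotypes overlapped for Sod1, Gpx1 and Pgd, with Keap1_KO B below WT D in each.

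Proteasome and respiratory chain genes were also higher as sets. All 31 proteasome genes had higher means in Keap1_KO (median 0.94, camera adjusted p = 2.24e-09, p = 0.227 with an estimated correlation), although in only 3 did all Keap1_KO arrays exceed all WT arrays and none passed adjusted over the list alone. Psmb1 differed by 2.14, Psmd4 by 1.60, the assembly factor Pomp by 1.58 and Psmb7 by 1.49. Of 33 genes of oxidative phosphorylation, 30 had higher means (median 0.66, camera adjusted p = 3.42e-05, p = 0.360 with an estimated correlation), among them Ndufs8 with 2.54 and Uqcrc1 with 1.63. The median of oxidative phosphorylation was 0.37 after repeated quantile normalization. Keap1_KO B read -0.28 for the proteasome list and -0.34 for oxidative phosphorylation, inside the WT range of both. Glycolysis genes (21 tested, median 0.45, camera adjusted p = 0.00731, p = 0.310 with an estimated correlation) included Aldoa with 1.40 and Pkm with 1.24. ATF4 and amino acid response genes (16 tested, median 0.58, camera adjusted p = 0.00493, p = 0.296 with an estimated correlation) included Shmt2 with 1.32 and Ddit3, a stress-induced transcription factor gene, with 1.23. The calls of glycolysis (adjusted p = 0.463), ATF4 genes (0.654) and oxidative phosphorylation (0.736) were lost with the first principal component of the arrays as covariate. The median of ATF4 genes was 0.37 after repeated quantile normalization, and that of glycolysis 0.28 with centred arrays. Over 17 alternatives their camera adjusted p, in the order glycolysis, ATF4 genes and oxidative phosphorylation, ranged from 1.07e-04 to 0.463, from 0.00146 to 0.654 and from 1.64e-08 to 0.736.

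**Figure D2:**
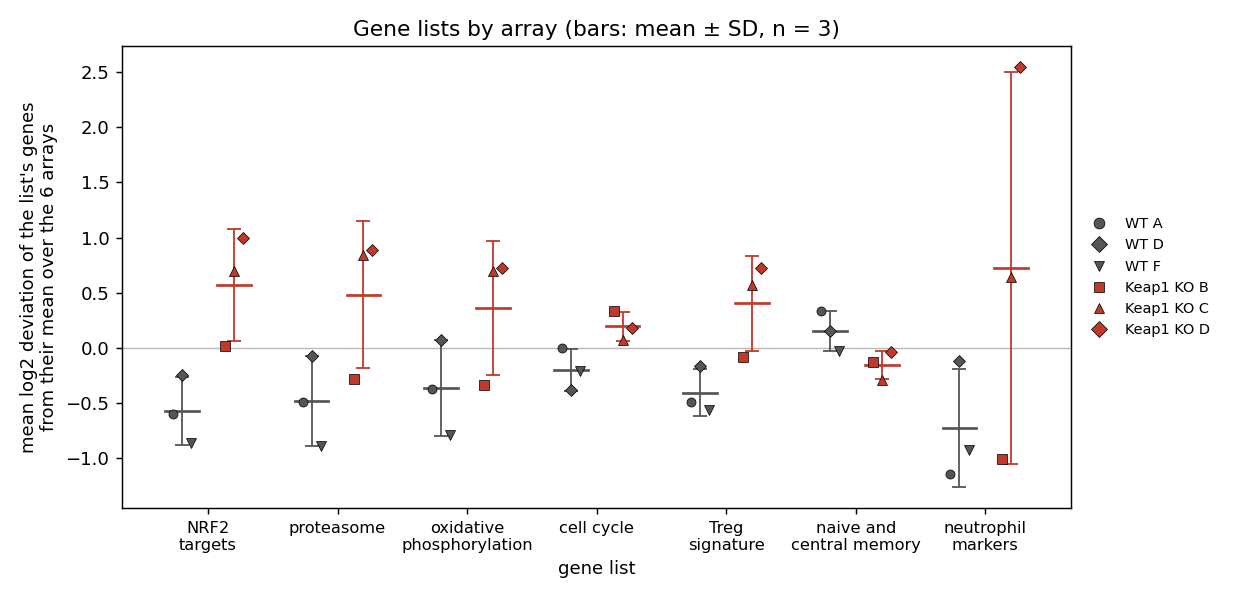
Mean log2 deviation of the genes of 7 lists from their mean over the 6 arrays (vertical axis), with 1 symbol per array, horizontal lines for group means and bars for the SD of 3 arrays. Keap1_KO B lies within or near the WT arrays for the NRF2, proteasome and oxidative phosphorylation lists, and Keap1_KO D stands far above the other arrays in the neutrophil markers, at 2.54.

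Genes of the Treg signature were higher as a set, while Il2ra, Ctla4 and Ikzf2 did not differ beyond the spread. Of 26 tested genes, 21 had higher means in Keap1_KO (median 0.62, camera adjusted p = 5.33e-04, p = 0.145 with an estimated correlation), and 2, Itgae and Capg (the latter named after its values were seen), passed adjusted over the list alone, whereas none did over all genes. Without Keap1_KO B the median was 0.94, and after repeated quantile normalization it was 0.37. The mean deviation of the list was -0.49, -0.16 and -0.56 on WT A, D and F. On Keap1_KO B, C and D it was -0.08, 0.57 and 0.72. Pan-CD4 T cell genes rose too, with a higher median (0.78) but a lower mean (0.60, against 0.81 for the Treg list). A rise was thus not confined to Treg genes, and the lists were not tested against each other. Itgae, the gene of the epithelial-homing integrin CD103, read 9.03 ± 0.35 and 11.43 ± 0.65 (5.29-fold), with limma adjusted p = 0.0118 over the list alone and 0.476 over all genes. The costimulatory receptor genes Tnfrsf18 (GITR) and Tnfrsf4 (OX40) differed by 2.35 and 2.01, and the chemokine receptor gene Ccr8 by 2.20. The arrays overlapped for all of these receptor genes, with Keap1_KO B (10.52, 12.77 and 9.14) below WT D (10.81, 13.06 and 9.55). Il2ra, which encodes the CD25 chain used for the isolation, read 13.93 ± 0.22 and 13.88 ± 0.30. Ctla4 read 12.13 ± 0.32 and 12.21 ± 0.15, a difference of 0.08 that was -0.18 after repeated quantile normalization and -0.088 with centred arrays, and Ikzf2, the gene of the transcription factor Helios, 15.27 ± 0.15 and 15.16 ± 0.35. The cluster that Foxp3 shares with neighbouring transcripts read 10.89 ± 0.22 and 11.87 ± 0.67, with Keap1_KO B (11.11) below WT F (11.15).

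Genes of naive and central memory T cells were the only set to pass in the lower direction with the preset correlation. Of 13 tested genes, 10 had lower means (median -0.41, camera adjusted p = 0.00298, p = 0.0471 before and 0.679 after adjustment with an estimated correlation). The median was -0.25 without WT A and -0.26 without Keap1_KO C. Dapl1 read 9.61 ± 0.22 in WT and 8.03 ± 0.07 in Keap1_KO, 2.99-fold lower, and passed adjusted over the list alone (limma adjusted p = 9.05e-04). The IL-6 receptor gene Il6ra differed by -0.89 and Foxp1, a transcription factor gene of quiescent T cells, by -0.81, whereas Klf2 differed by 0.83 in the other direction. Pan-CD4 T cell genes were higher (14 tested, median 0.78, camera adjusted p = 0.00298, p = 0.242 with an estimated correlation), with 1.04 for Cd4, 0.96 for Cd3e and 1.12 for Lat. Immediate early genes (21 tested, median 0.52, camera adjusted p = 0.00323, p = 0.228 with an estimated correlation) included Zfp36 with 1.36 and Fos with 0.89, and their median was 0.30 without WT F. After repeated quantile normalization the medians were -0.65 for naive and central memory genes, 0.51 for pan-CD4 genes and 0.31 for immediate early genes. With the first principal component as covariate the calls of immediate early genes (adjusted p = 0.507) and pan-CD4 genes (0.314) were lost, and over 17 alternatives the camera adjusted p had a lowest value of 3.48e-05 for both and these highest values. Cell cycle genes had a small median of 0.33 with 30 of 34 higher (camera adjusted p = 1.46e-04, p = 0.056 with an estimated correlation), led by the replication licensing gene Mcm3 with 1.24. The cell cycle call was lost without Keap1_KO B (adjusted p = 0.075) and with array weights (0.117), in a range of camera adjusted p from 2.11e-13 to 0.117 over 17 alternatives, and the median was 0.16 with each array centred on its median.

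Markers of other cells differed most on single arrays. Neutrophil and granulocyte genes were higher as a set (15 tested, 14 with higher means, median 1.45, camera adjusted p = 0.00298, p = 0.372 with an estimated correlation), and the call was lost without Keap1_KO D (median 0.48, adjusted p = 0.112), in a range of camera adjusted p from 2.94e-05 to 0.971 over 17 alternatives. Without Keap1_KO B the median was 2.56. Their mean deviation was -1.01, 0.64 and 2.54 on Keap1_KO B, C and D and -1.14, -0.12 and -0.92 on WT A, D and F. Ngp, a neutrophil granule protein gene, read 8.02 ± 0.26 and 10.70 ± 3.04, and Camp read 9.36 ± 0.68 and 11.85 ± 3.49. Keap1_KO D, the array with the most neutrophil signal, also had the highest mean deviation in the markers of NK cells (1.56), plasma cells (1.20), B cells (0.90), erythroid cells (0.77) and macrophages and monocytes (0.76), and in the NRF2, proteasome, oxidative phosphorylation and Treg lists. Marker lists that did not pass were those of NK cells (median 0.83, adjusted p = 0.13), B cells (0.43, 0.221), plasma cells (0.41, 0.383), erythroid cells (0.33, 0.358), macrophages and monocytes (0.13, 0.374), dendritic cells (-0.11, 0.374), platelets and megakaryocytes (-0.15, 0.335) and stroma and endothelium (-0.04, 0.555). Without WT D the NK cell list (median 1.35, adjusted p = 0.00681) and the B cell list (0.87, 0.00681) passed, as they did without Keap1_KO C (NK cells 1.28, 0.0223, and B cells 0.84, 0.00221), and the plasma cell list passed without Keap1_KO B (1.15, 0.0484). Without WT F the medians were -0.023 for NK cells (adjusted p = 0.608), 0.019 for B cells (0.960) and 0.17 for plasma cells (0.708), and without Keap1_KO D they were 0.27, 0.21 and 0.0065, and none passed. With no intensity filter the NK cell (adjusted p = 0.0151) and B cell lists (0.0199) passed, and the NK cell list did with centred arrays (0.0235). The plasma cell list passed in the lower direction with the first principal component (-0.34, 0.00558) or the neutrophil markers (-0.22, 0.027) as covariate. The camera adjusted p over 17 alternatives ranged from 0.00681 to 0.923 for NK cells, from 0.00221 to 0.971 for B cells and from 0.00558 to 0.726 for plasma cells. The median of macrophage and monocyte genes turned to -0.044 with each array centred on its median. The CD8 T cell list had 2 tested genes and was not tested.

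The T helper lists and the remaining lists did not pass either, at the filter and scale used throughout. The median and adjusted p were 0.43 and 0.0541 for Th1 and cytotoxic effector genes, -0.13 and 0.906 for Th2 genes, 0.36 and 0.172 for Th17 and Tfh genes, and 0.22 and 0.0557 for coinhibitory and exhaustion genes. Without WT D the Th1 list (median 0.62, adjusted p = 0.00319) and heme and iron handling (0.53, 0.0137) passed. Without Keap1_KO C the Th1 list (0.56, 0.00293), heme and iron handling (0.38, 0.0167) and the coinhibitory list (0.31, 0.0172) passed. Without WT F the medians of the Th1 list (0.17, 0.441) and of heme and iron handling (0.24, 0.206) were lower and neither passed. With all arrays and no intensity filter the Th1 list (adjusted p = 0.00105), heme and iron handling (0.00163) and the coinhibitory list (0.00163) passed, and with centred arrays the Th1 list (0.0142) and heme and iron handling (0.0462) did. Heat shock passed in the lower direction with the first principal component as covariate (-0.47, 0.023), in a range of camera adjusted p from 0.023 to 0.986. The camera adjusted p over 17 alternatives ranged from 0.00105 to 0.923 for the Th1 list, from 0.00163 to 0.372 for heme and iron handling and from 0.00163 to 0.24 for the coinhibitory list. Single members, named after their values were seen, passed adjusted over their list alone, and none did over all genes: Bhlhe40 (1.46) and Il18r1 (1.11) in the Th1 list, the chemokine receptor gene Ccr4 (2.43) in the Th2 list and the clock repressor gene Nr1d1 (0.99) in the circadian list. Heme and iron handling had 0.41 and 0.0549, cholesterol synthesis 0.12 and 0.383, fatty acid synthesis 0.20 and 0.557, type I interferon response 0.08 and 0.374, heat shock 0.13 and 0.921, p53 targets 0.08 and 0.921, the circadian clock 0.0099 and 0.949, and sex genes -0.12 and 0.221. The medians of type I interferon response (-0.12), heat shock (-0.28), p53 targets (-0.055) and the circadian clock (-0.055) were negative after repeated quantile normalization, as they were with each array centred on its median, and that of cholesterol synthesis (-0.049) was negative with centring alone. Median, mean and test direction differed in sign for 4 lists: platelets and megakaryocytes, type I interferon response, Th2 effector and p53 targets. Of the 34 lists tested, 14 passed with the preset correlation, 13 higher and 1 lower, and 0 passed with an estimated correlation (smallest adjusted p 0.679) or with directional fry (0.196). The mixed fry test counts members changing in either direction and so gives no direction for the set. It passed for the naive and central memory list only (adjusted p = 0.00672).

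Single genes did not pass the threshold over all genes. Among genes with unadjusted p under 0.01 and no overlap, none past the adjusted threshold, the largest higher values in Keap1_KO were those of Il1r2, the decoy receptor for interleukin-1, which read 7.05 ± 0.77 and 11.47 ± 1.5 (21.4-fold), followed by Nqo1. Next came the histone gene Hist1h2aj (11.9-fold), of a family with near-identical members, the interferon-induced membrane protein gene Ifitm2 (8.30-fold), Sva (8.30-fold) and Gstm1 (7.32-fold). The WT values of Nqo1 and Sva lay below the array medians, so their folds and places in this order are uncertain. The largest lower values were those of Ugcg, the glucosylceramide synthase gene, which read 11.42 ± 0.13 and 9.80 ± 0.81 (3.07-fold lower), Dapl1 (2.99-fold), Btbd35f12 (2.15-fold), Ifi213 (2.03-fold), Ly6g5b (1.91-fold) and Il6st, the shared receptor chain of the IL-6 family (1.89-fold). The same holds for Btbd35f12, whose Keap1_KO values lay below the array medians.

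By limma, 0 of 16825 genes had adjusted p under 0.05, and the smallest adjusted p was 0.258. At unadjusted p under 0.05 there were 1733 genes, 1410 higher and 323 lower in Keap1_KO, against 841 that chance alone would give. The groups did not overlap for 1532 genes higher and 835 lower, 14.1% of all, where chance gives 10%. Of the genes at unadjusted p under 0.05, 81.4% were higher, and this share was 60.8% after repeated quantile normalization and 53.1% with each array centred on its median, so the excess of higher values depends on the scaling. The median difference over all genes was 0.06 as deposited and -0.11 with centred arrays, and every direction is relative to the scale used. Without Keap1_KO B, 569 genes passed the adjusted threshold (542 higher and 27 lower), and with array weights, which gave that array the lowest weight, 1880 did (1612 higher and 268 lower). With a trended and robust spread estimate 1 gene passed, the predicted gene Gm20658 (4.78 ± 0.11 and 6.56 ± 0.08, with WT values below the array medians, named after its values were seen), and with no moderation 0 did. Higher genes at unadjusted p under 0.05 numbered 614 without WT A, 580 without WT F, 3399 without Keap1_KO B, 459 without Keap1_KO C and 430 without Keap1_KO D. Lower genes numbered 200 without WT A, 1153 without Keap1_KO B, 122 without Keap1_KO C and 135 without Keap1_KO D.

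The arrays also differed in a way that crossed the genotypes. The first principal component took 66.6% of the variance and placed WT A, D and F at -37.1, 4.54 and -70.0 and Keap1_KO B, C and D at -30.0, 60.5 and 72.1 (exact permutation p = 0.2). The median deviation of the 1403 small RNA genes ran the opposite way on the arrays at both ends, with 0.64 on WT F and -0.41 on Keap1_KO D (exact permutation p = 0.3 between genotypes). The labels name no batch, so no value within batches could be computed.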

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

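The erythroid gene test of the globin clusters was chosen after their values had been seen, and its gene list was fixed before. Clusters carrying several gene symbols stood outside the gene comparison. Of 1267 such clusters passing the intensity filter, 6 met the bounds for a closer look. These were a rise in Keap1_KO of at least log2 2, limma unadjusted p under 0.01 and every Keap1_KO array above every WT array. Over the 16342 clusters without a single symbol, limma gave 0 with adjusted p under 0.05. It gave 835 with unadjusted p under 0.05, about as many as chance alone would give. All 6 had limma adjusted p = 0.676, so none passed the adjusted threshold. The fit of every cluster passing the filter, named or not, also gave 0.

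The largest was a cluster shared by the beta-globin genes Hbb-bt, Hbb-b2, Hbb-bs and Hbb-b1, which read 9.63 ± 0.26 in WT and 14.07 ± 0.96 in Keap1_KO (mean ± SD, n = 3), a difference of 4.44. A further cluster of the same genes differed by 2.59. Clusters shared by Hist1h2b genes differed by 3.90, 3.44 and 2.26, and a cluster shared by Hist1h2a genes by 2.87. Keap1_KO B had 13.03 in the largest globin cluster, against 9.34 to 9.85 on the WT arrays.

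The globin clusters were set against red blood cells carried over into the isolate. The clusters shared by Hba-a1 and Hba-a2 were higher too, by 2.60 and 2.93, and every Keap1_KO array exceeded every WT array in them. The erythroid list, without the globins, had a median of 0.33 over 8 tested genes (camera adjusted p = 0.358), with Car2 at 1.68, Car1 at 0.81, Slc4a1 at 0.17 and Alas2 at -0.39. Of the 8 genes 7 were higher and only Alas2 was lower, but the list did not pass and 7 of its 18 genes had no cluster of their own, so carry-over and a change within the cells cannot be told apart. Among the WT arrays, WT F read highest in the Hba clusters (9.47 and 11.82) and in the mean deviation of the erythroid list (0.12). In the largest beta-globin cluster WT F (9.85) lay close to WT A (9.71). On Keap1_KO B, where the Hba clusters read highest (10.73 and 13.19), the mean deviation of the erythroid list was -0.36, inside the WT values of -0.50, -0.27 and 0.12. There Car1 read 7.00, the lowest of all arrays, whereas Car2 (7.67) and Slc4a1 (5.51) lay above the WT arrays. Slc4a1 and Rhag averaged 5.36 and 5.45 in WT, dim beside the globin clusters, so a carry-over seen in globin need not move such genes. This is a single array with members going both ways, so its values do not decide for or against carry-over there. The list lay above the WT arrays on Keap1_KO C (0.24) and Keap1_KO D (0.77). A difference in beta-globin haplotype between the mice and a change of blood formation in the knockout stay open, as neither was tested.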

How the results depend on the processing

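The covariates, the protein-coding subset and the omission of WT F and Keap1_KO D together were chosen after the data had been seen. No paired analysis was possible because the replicate letters of the groups share only D and no label pairs the arrays. Keap1 and Nfe2l2 have 1 cluster each, so testing their clusters separately gave no further value. Keap1 and Slc7a11 on most arrays, and Nqo1 on the WT arrays, lay below the array median, so the size of their differences is uncertain.

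No gene passed the limma adjusted threshold as first analysed, whereas 1733 had unadjusted p under 0.05. The adjusted count ranged from 0 to 569 when single arrays were left out, with 569 without Keap1_KO B and 0 without each other array. It was 1880 with array weights and 1 with a trended and robust spread estimate. It was 0 with no moderation, with each filter, normalization and covariate, with protein-coding genes only, without WT F and Keap1_KO D together, at adjusted p under 0.1 and with a 1.5-fold minimum. Unadjusted p under 0.05 with at least 2-fold gave 699. Of the 569 genes, 551 also passed with array weights, which were lowest for Keap1_KO B (0.352) and highest for WT A (3.38), and Keap1_KO B lay beyond every WT array in 290 of them (51.0%). The weights changed the say of all 6 arrays at once, and the cause of either count was not tested.

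Genes higher at unadjusted p under 0.05 numbered 1410 and ranged from 430 to 3399 when single arrays were left out: 614 without WT A, 580 without WT F, 3399 without Keap1_KO B, 459 without Keap1_KO C and 430 without Keap1_KO D. Genes lower numbered 323 and ranged from 122 to 1153: 200 without WT A, 1153 without Keap1_KO B, 122 without Keap1_KO C and 135 without Keap1_KO D. Lower genes numbered 904 with no intensity filter, 928 over every cluster with or without a symbol, 730 after repeated quantile normalization and 881 with each array centred on its median. With no moderation 835 were higher, and with array weights 4181 were higher and 1716 lower. With the small RNA index as covariate 566 were higher, with the first principal component 427, with the neutrophil markers 403 (and 156 lower), and without WT F and Keap1_KO D together 224 (and 208 lower). Without WT D 1713 were higher and 295 lower. The cause of these moves was not tested.

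Keap1 and Nfe2l2 kept their direction and stayed short of the adjusted threshold in every alternative run. The correlation of the closest pair of different genotype, 0.988, moved by less than the spread of the correlations within genotypes in the 4 alternatives run for it. Lists passing numbered 14, and 12 to 18 when single arrays were left out, where 12 to 14 of the 14 kept their call. They numbered 9 with the small RNA index as covariate, all of them among the 14, and 9 with the first principal component, of which 7 were. With the neutrophil markers 10 passed (9 of the 14), without WT F and Keap1_KO D together 8 (all among the 14), and with an estimated correlation or directional fry 0. The NRF2, glutathione, thioredoxin, proteasome, Treg and naive and central memory lists passed in the same direction in all 17 alternatives that kept the preset correlation. With an estimated correlation the NRF2 median of 0.94 and the Treg median of 0.62 had adjusted p = 0.679, and with fry 0.196 and 0.205. The estimated correlations were 0.390 and 0.190, against the preset 0.01. Among the lists that passed, they were highest for the proteasome (0.862), neutrophils (0.821) and oxidative phosphorylation (0.776). The lowest was that of the naive and central memory list (0.046). The higher the estimate lies above the preset, the more the preset camera p understates the uncertainty.

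Several list medians changed sign, and among the lists that had passed these were oxidative phosphorylation and neutrophils. With no intensity filter, type I interferon response was -0.088 and the circadian clock -0.0069. After repeated quantile normalization, type I interferon response was -0.12, heat shock -0.28, p53 targets -0.055 and the circadian clock -0.055. With centred arrays, cholesterol synthesis was -0.049, type I interferon response -0.088, heat shock -0.040, p53 targets -0.087, the circadian clock -0.16 and macrophages and monocytes -0.044. With array weights the circadian clock was -0.11 and stroma and endothelium 0.058. The cause was not tested.

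With the small RNA index as covariate, cholesterol synthesis was -0.050, fatty acid synthesis -0.065, type I interferon response -0.10, heat shock -0.20, p53 targets -0.028, the circadian clock -0.10, B cells -0.0042, plasma cells -0.11 and NK cells -0.32. With the first principal component, Th1 genes were -0.10, Th2 genes 0.12, Th17 and Tfh genes -0.025, oxidative phosphorylation -0.031, cholesterol synthesis -0.093, fatty acid synthesis -0.14, type I interferon response -0.054, heat shock -0.47, p53 targets -0.027 and the circadian clock -0.13. There B cells were -0.078, plasma cells -0.34, NK cells -0.50, neutrophils -0.073, dendritic cells 0.023 and platelets and megakaryocytes 0.0038. With the neutrophil markers, fatty acid synthesis was -0.090, heat shock -0.23, the circadian clock -0.046, plasma cells -0.22, NK cells -0.12, neutrophils -0.027, erythroid cells -0.032 and stroma and endothelium 0.020. Without WT F and Keap1_KO D together, Th1 genes were -0.075, cholesterol synthesis -0.015, fatty acid synthesis -0.14, type I interferon response -0.037, heat shock -0.23, p53 targets -0.052, the circadian clock -0.10, B cells -0.16, plasma cells -0.13, NK cells -0.32 and macrophages and monocytes -0.021. The neutrophil covariate is built from the neutrophil list, and for the rest the cause was not tested.

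When single arrays were left out, medians ranged from -0.16 to 0.12 for stroma and endothelium, from -0.27 to 0.017 for Th2 genes, from -0.16 to 0.029 for dendritic cells, from -0.034 to 0.12 for type I interferon response, from -0.13 to 0.37 for heat shock, from -0.011 to 0.13 for p53 targets and from -0.088 to 0.12 for the circadian clock. They ranged from -0.023 to 1.35 for NK cells, from -0.013 to 0.41 for macrophages and monocytes and from -0.035 to 0.50 for fatty acid synthesis. The range was 0.019 to 0.87 for B cells, 0.0065 to 1.15 for plasma cells, 0.17 to 0.62 for Th1 genes and 0.24 to 0.53 for heme and iron handling, with the lowest values without WT F, except for plasma cells without Keap1_KO D.

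Medians of lists that passed also moved with the scaling and with the covariates. After repeated quantile normalization they were 0.20 for NADPH production, 0.37 for the Treg signature, -0.65 for naive and central memory genes, 0.37 for oxidative phosphorylation, 0.37 for ATF4 genes, 0.31 for immediate early genes and 0.51 for pan-CD4 genes. With centred arrays they were 0.15 for NADPH production, 0.16 for the cell cycle and 0.28 for glycolysis. With the first principal component as covariate they were 0.51 for NRF2 targets, 0.43 for glutathione, 0.26 for thioredoxin, 0.11 for NADPH production, 0.27 for the Treg signature, 0.13 for glycolysis, 0.038 for ATF4 genes, 0.090 for immediate early genes, 0.18 for the proteasome, 0.12 for pan-CD4 genes and 0.51 for the cell cycle. The cause was not tested.

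Of 1734 values of 92 genes under the alternatives, 1591 kept their direction and their side of the adjusted threshold, 124 passed it (75 with array weights, 48 without Keap1_KO B and 1 with a trended and robust spread estimate) and 19 changed sign, in 5 genes. Ctla4 was -0.18 after repeated quantile normalization, -0.088 with centred arrays and -0.037 with the neutrophil markers as covariate, and ranged from -0.093 to 0.23 when single arrays were left out. Ikzf2 was 0.10 with the small RNA index, 0.27 with the first principal component, 0.15 with the neutrophil markers and 0.082 without WT F and Keap1_KO D together, and ranged from -0.31 to 0.012 when single arrays were left out. Il2ra was 0.094 with the neutrophil markers and 0.047 without WT F and Keap1_KO D together, and ranged from -0.20 to 0.10 when single arrays were left out. With the first principal component Camp was -0.41 and Mmp8 -0.48, with the neutrophil markers they were -0.24 and -0.32, and Mmp8 was -0.014 without WT F and Keap1_KO D together. The cause was not tested.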

Other observations

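The tests with the first principal component or the neutrophil markers as covariate, the count of NRF2 targets on Keap1_KO B, the intervals and estimated correlations of the covariate fits, and the comparisons of Keap1_KO B with WT D minus WT A and WT D minus WT F were chosen after the results had been seen, as were the genes of the next paragraph.

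The genes named here form no list fixed beforehand, were not tested together, and did not pass the limma adjusted threshold over all genes (adjusted p = 0.476 each). Those given as higher had every Keap1_KO array above every WT array. S100a4 read 14.68 ± 0.55 in WT and 16.52 ± 0.36 in Keap1_KO, S100a6 11.84 ± 0.39 and 13.38 ± 0.33, and the galectin-1 gene Lgals1 13.21 ± 0.45 and 15.44 ± 0.91. The receptor genes Ccr4, Gpr15, Il18r1 and Tnfrsf1b differed by 2.43, 2.27, 1.11 and 1.12. The metallothionein genes Mt1 and Mt2 differed by 1.72 and 0.96. The histone genes H1f5 and H2ac10, of families with near-identical members, differed by 2.73 and 2.84.

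The NRF2, proteasome and oxidative phosphorylation lists were all higher in Keap1_KO, on arrays that also differed along the first principal component. With that component as covariate the NRF2 median was 0.51 instead of 0.94 (camera adjusted p = 1.25e-06, and adjusted p = 0.229 with an estimated correlation). With the neutrophil markers it was 0.56 (camera adjusted p = 2.21e-10, and adjusted p = 0.420 with an estimated correlation). Over 17 alternatives at the preset correlation the camera adjusted p ranged from 1.20e-13 to 1.25e-06. The 95% interval of the list mean over arrays, with 3 residual degrees of freedom, was 0.26 to 0.83 with the component and 0.087 to 1.35 with the markers. The list median lay at percentile 100 of 10000 random lists matched on expression, whose highest median was 0.60. The same comparison put the proteasome list at percentile 100, oxidative phosphorylation at 99.9 and the Treg signature at 99.8, so it does not set the NRF2 list apart. Both intervals were positive, but they take no account of error in the covariates. The component and the markers were taken from the same arrays and correlated with genotype (r = 0.66 and 0.56). Limma fry gave adjusted p = 0.116 with the component and 0.417 with the markers. These fits therefore cannot exclude array-wide signal or neutrophils as the whole cause of the NRF2 difference, and the percentile bears on expression level alone.

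The proteasome list had a median of 0.18 with the component as covariate (camera adjusted p = 0.0057, in a range from 5.16e-14 to 0.0057, and adjusted p = 0.229 with an estimated correlation), down from 0.94. The interval of its mean, 0.011 to 0.35, lay only just above 0 and takes no account of error in the component. Array-wide signal may therefore account for most or all of this difference. The oxidative phosphorylation list went from 0.66 to -0.031 (adjusted p = 0.736, in a range from 1.64e-08 to 0.736), so array-wide signal may account for it. The component is partly confounded with genotype, so the covariate also takes up part of a genotype effect, and more respiratory chain transcripts in the knockout stay open.

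Keap1_KO B lay with the WT arrays across the transcriptome. A wrong label would leave it among the WT arrays in NRF2 targets, yet it lay above all 3 WT arrays in 15 of 26 targets, against 18.9% of all genes (one-sided exact binomial p = 1.3e-05 over targets, which are not independent replicates), and its Nqo1 value was 8.50 against at most 5.03 in WT, which argues against a mislabelled sample. For array-wide signal, the profile of Keap1_KO B minus the mean of Keap1_KO C and D was compared across genes with WT A minus WT F, and r was -0.315, short of the bound of -0.5 set before r was computed for calling it the cause. The pairs added afterwards gave -0.536 for WT D minus WT A and -0.640 for WT D minus WT F, so the bound lay within the spread of r between WT pairs. Whether array-wide signal or a weaker response in that sample sets Keap1_KO B apart therefore cannot be told apart.

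Other splits of the 6 arrays into 3 and 3 bear on these counts, and with 10 splits the share can never be under 0.1. The real split gave 1733 genes at unadjusted p under 0.05, and 2 of the 10 splits, itself included, gave as many. The highest other was 5210, for WT A, WT F and Keap1_KO B against WT D, Keap1_KO C and Keap1_KO D, which points to a structure of the samples that crosses the genotypes. The real split passed 14 lists and the highest other 15, and 2 of 10 splits, the real one included, passed at least 14. All 10 splits gave 0 genes past the limma adjusted threshold, with a highest other of 0. The NRF2 median, taken without its sign, was 0.94 in the real split and 0.91 in the highest other, so 1 of 10 splits reached it. That other was again WT A, WT F and Keap1_KO B against WT D, Keap1_KO C and Keap1_KO D. That split exchanges only WT D and Keap1_KO B between the genotypes, so a genotype effect would also enter its 5210 genes and its median of 0.91. The NRF2 list thus shifted almost as much along that split as along genotype, but these shifts are not independent.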
